A study of Arabidopsis thaliana with 148 samples.

How the data were processed

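The intensities used here are the background-subtracted Cy3 signals that the authors deposited as raw scanner tables for each array (column gProcessedSignal), written by Agilent Feature Extraction 9.5.3.1 per the file headers. The series value tables held the same numbers on every spot compared (largest relative difference 0), so they were not run as a separate alternative. Reads, mapping and variant calls do not belong to this kind of data. The probe annotation, coordinates and flags came from the array files, whose headers name the array design's build as ath1. The table of gene symbols given with the data (assembly TAIR10.1) was used for names only. How slides were washed, which plates plants shared, the hour of harvest and the names behind the stock codes are not given in the sources used here. Whether a probe lies in an exon, an intron or an untranslated region is not given in the sources used here either.

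All arrays were kept, 2 for each of 74 accessions. Control spots were left out, which left 34262 probes of 60 bases, each on 1 spot per array: 26649 for annotated genes, 5876 for sORFs, 1446 for other transcripts and 291 for several features at once. Probes of the last 2 classes entered the fit but no comparison of genes with sORFs. Each gene had 1 probe, so taking the mean of a gene's probes was not applicable. A symbol was used where the table paired it with the locus, which held for 10292 genes. In the files 974 spots were marked by the image software, on 941 probes, and their values were left out of the fits and means. An accession with 1 marked spot thus rests on its other array for that probe. In all 8 probes were saturated on at least 1 array, and an alternative leaves them out.

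Signals were taken to log2 and scaled by subtracting the 75th percentile of the array, which ran from 449 to 2216 units. A probe was kept where it was well above background, by the flag in the files, on both arrays of at least 1 accession. That left 24673 probes, 21887 of genes and 1529 of sORFs. The dim end differs between arrays because a fixed detection floor falls lower after scaling on a bright array, from -7.84 up to -4.74 on the log2 scale. An alternative therefore lifts every value under -4.74 to that value.

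Batches were read from the file headers: 11 scan days in 3 periods parted by gaps of over 30 days, 37 slides and 2 scanners. Period 1 held 20 accessions with their replicates on different slides and days. Periods 2 and 3 held 32 and 22 accessions with both replicates on 1 slide, so slides and accessions overlap in part and periods and accessions fully. Each comparison is therefore given also with the slide or the period as a block, and the central ones within single periods.

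Differences among the 74 accessions were tested with the moderated F-test of limma 3.58.1 (73 and 74 degrees of freedom, prior degrees of freedom 4.36) with a mean-variance trend. All p-values measure the spread between these samples. They were adjusted by the Benjamini-Hochberg method over all probes tested, with a threshold of 0.05. Repeatability is the share of variance between accessions in a 1-way analysis of variance. The strict rule asks in addition for a repeatability of at least 0.5 and a span of at least 2 between the highest and the lowest accession mean. Single accessions were set against the mean of the other 73 with moderated t-tests in the same fit, adjusted within each contrast, with a difference of at least 1. With a block the contrast is against the other accessions of the same slides or period. The span is then taken over deviations from the mean of those accessions.

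The comparison of sORFs with genes permuted class labels 100000 times within 20 bins of mean signal, so its p-value rests on the spread between probes and not between samples. An on and off gene is one well above background on both arrays of at least 4 accessions and on neither array of at least 4, with a bound of at least 8-fold. Fisher's exact test compared the states of neighbouring genes in pairs chosen after the values were seen.

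The 16 gene lists and the 15 relations were written from textbook knowledge before the data were examined. The lists were glucosinolate, flowering time, circadian clock, salicylic acid defence, NLR immune receptors, jasmonate and ethylene defence, anthocyanin and flavonoid, photosynthesis, cold and drought response, iron and copper status, known small peptides, 20S proteasome, reference genes, root markers, floral organ markers and senescence. The last 3 served as markers of other organs or stages. A list's score is the mean of its members' z-scores on an array, tested by an F statistic with arrays permuted 100000 times, and with slides as blocks 20000 times. The spread of members was set against 10000 random lists of the same size and matched signal. Correlations over accession means were tested by 100000 permutations, pooled and within periods, and adjusted over 15 relations and over 39 relations with marker lists. A 16th relation, of *IMA1* with *FER1*, was not run because the symbol *IMA1* was not paired.

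The genes named in the text were picked by rule: the 12 named genes and 6 sORFs of largest spread, the 3 named genes of smallest spread, and of each list the 4 members of largest and the 1 of smallest spread. To these come the genes of the fixed relations, the 8 named on and off genes of largest bound, and the 3 named genes highest and lowest in each of the 5 accessions with most genes apart. One gene picked by this rule is not reported here.

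Alternatives run were normexp background correction with quantile normalization, quantile normalization, other detection filters, blocks for slide, scan day, period and replicate number, slide as a random effect, limma without trend, the common floor, saturated or cross-hybridising probes left out, each period alone, 2 accessions left out, and 100 arrays drawn at random left out singly. The procedure was tested on simulated data made from the arrays' own spread. In 200 probes each it recovered 68.5%, 90.0% and 100% of accession effects with an SD of 0.25, 0.5 and 1, called 0.133% of probes without an effect, and recovered 38.0% and 92.5% of single-accession shifts of 1 and 2. A slide effect alone was called in 89.4% of probes without the block and in 0% with it.

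Calculations used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Genome sequences of the accessions were not used here, nor were other expression data.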

Results

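The arrays measured transcript levels in the aerial parts of 18-day-old seedlings of 74 accessions of *Arabidopsis thaliana*, lines of the species kept as separate seed stocks and named here by their stock codes. The plants grew on agar plates of MS medium, a standard mixture of plant nutrients, and each accession was measured in 2 biological replicates, each hybridised to 1 single-colour (Cy3) array. Each array carried 34262 probes of 60 bases outside its controls. Of these, 26649 stood for annotated genes, 5876 for small open reading frames (sORFs, short reading frames outside the annotated genes), 1446 for other transcripts and 291 for several features at once. No accession was named as a control, so the comparisons ask which genes and sORFs differed among the accessions, and by how much against the spread between replicates. The 75th percentile of the signal ran from 449 to 2216 units per array, and between 17825 and 21927 probes per array were well above background (median 20526.5), so dim probes were the least precisely measured. Levels are given as log2 signal relative to the 75th percentile of the array, as the mean ± SD of the 2 arrays of an accession unless another error is named. The arrays were scanned in 3 periods set apart by gaps of over 30 days, which held 20, 32 and 22 accessions, and no accession was scanned in more than 1 period.

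The replicates of an accession resembled each other more than any other array in nearly all cases. For 146 arrays, all but 2, the most similar array over 24129 probes was the other replicate of the same accession. The median Pearson correlation across probes was 0.992 between replicates (lowest 0.963, highest 0.995), against 0.946 between accessions on the same slide, 0.938 between accessions of the same period and 0.929 between accessions of different periods. The exceptions were the second array of CS22574, closest to CS22695 (0.984, against 0.963 with its partner), and the first array of CS22693, closest to CS22680 (0.985, against 0.979). These correlations are across probes, which are not independent replicates. In periods 2 and 3 both arrays of an accession lay on 1 slide, so the spread between replicates there leaves out differences between slides. The median repeatability of genes detected on all arrays was 0.795, 0.885 and 0.886 in the 3 periods. Over the same genes, the mean square between slides was 2.14 times that between accessions of a slide in period 2 and 1.48 times in period 3 (medians), and the mean square between periods was 8.83 times that between accessions of a period.

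Annotated genes were detected far more often than sORFs in every accession. A median of 70.0% of the gene probes was well above background on both arrays of an accession (63.1% to 72.3% over 74 accessions), against 7.91% of the sORF probes (2.94% to 10.9%). The difference of sORFs minus genes had a median of -61.8 percentage points and ran from -65.0 to -56.0, so that it had the same sign in all 74 accessions. In at least 1 accession 82.1% of the gene probes and 26.0% of the sORF probes were detected, and on all arrays 14729 genes and 95 sORFs. The median share of sORFs detected was 5.94%, 8.09% and 9.69% in periods 1, 2 and 3, and that of genes 70.2%, 68.3% and 71.2%. A probe under background was not detectable at this signal, which does not show that the transcript was absent.

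**Figure D1:**
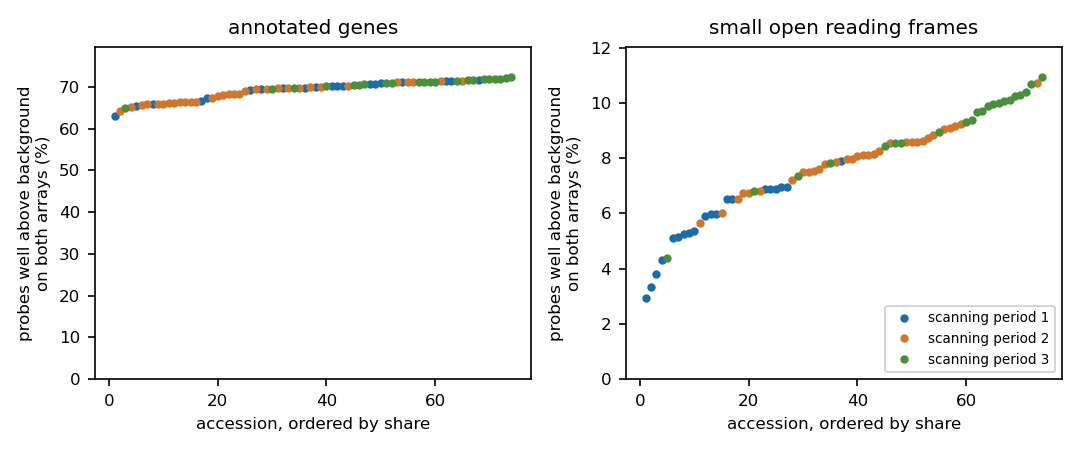
Share of probes well above background on both arrays (vertical axis, percent) in each of 74 accessions, ordered by that share (horizontal axis), for annotated genes on the left and sORFs on the right. Each point is 1 accession coloured by scanning period, the 2 panels have different scales, and every sORF share (highest 10.9%) lies below every gene share (lowest 63.1%).

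Among genes detected in at least 1 accession, transcript levels differed among accessions nearly everywhere. The widest spread was that of *PSRP6* (AT5G17870), a protein of the chloroplast ribosome encoded at chromosome 5, 5907819 to 5908139 on the plus strand. Its level was 6.13 ± 0.43 in CS22570 and not well above background in CS917, a difference of at least 15401-fold, and the SD of its 74 accession means was 6.76. *AOP2* (AT4G03060; chromosome 4, 1351980 to 1353148, minus strand), the dioxygenase that makes alkenyl glucosinolates, reached 7.29 ± 0.15 in CS22679, at least 21168-fold above CS22747. *RPP5* (AT4G16950; chromosome 4, 9539029 to 9544359, minus strand), an immune receptor of the NLR class that recognises downy mildew, reached 4.55 ± 0.10 in CS22636, at least 4003-fold above CS6824. *XTH7* (AT4G37800; chromosome 4, 17775697 to 17777366, minus strand), of the family of enzymes that remodel cell wall xyloglucan, was 4.34 ± 0.01 in CS22691, at least 3814-fold above CS6918. For a dim accession only a bound can be given. It sets the mean of the brighter accession against, on each dim array, the higher of the lowest signal that was well above background and the spot's own signal.

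The other genes of widest spread were of several kinds. The defence genes *TIR* (AT1G72930, a Toll/interleukin-1 receptor domain protein), *RLM3* (AT4G16990, needed for resistance to the fungus that causes blackleg) and *CSA1* (AT5G17880, an NLR receptor) differed by at least 14918-, 2515- and 1007-fold between their highest and lowest accession. *HTB9* (AT3G45980), a histone H2B, differed by at least 2277-fold, and *PLC8* (AT3G47290), of the phosphoinositide-specific phospholipase C family, by at least 1443-fold. *Fes1C* (AT5G02150), related to nucleotide exchange factors of HSP70 chaperones, *TAF7* (AT1G55300), a subunit of the general transcription factor TFIID, and *Hsp81.4* (AT5G56000), a cytosolic HSP90 chaperone, differed by at least 1317-, 811- and 771-fold. The adjusted p of these 12 genes ran from 1.52e-42 (*RPP5*) to 3.87e-85 (*XTH7*) in limma's moderated F-test, and with the slide as a block from 5.52e-39 (*RPP5*) to 1.75e-75 (*XTH7*). At the other end were the named genes of smallest spread among those well above background on all arrays. *GTF2H2* (AT1G05055), a subunit of the transcription and repair factor TFIIH, varied over 1.47-fold between its highest and lowest accession, *IMPA-4* (AT1G09270), an importin alpha that carries proteins into the nucleus, over 1.48-fold, and *DPMS1* (AT1G20575), a dolichol phosphate mannose synthase, over 1.62-fold. Their SDs of accession means were 0.12, 0.13 and 0.12 against replicate SDs of 0.06, 0.08 and 0.08, and they too passed the F-test (adjusted p = 1.29e-14, 1.62e-11 and 3.33e-10).

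**Figure D2:**
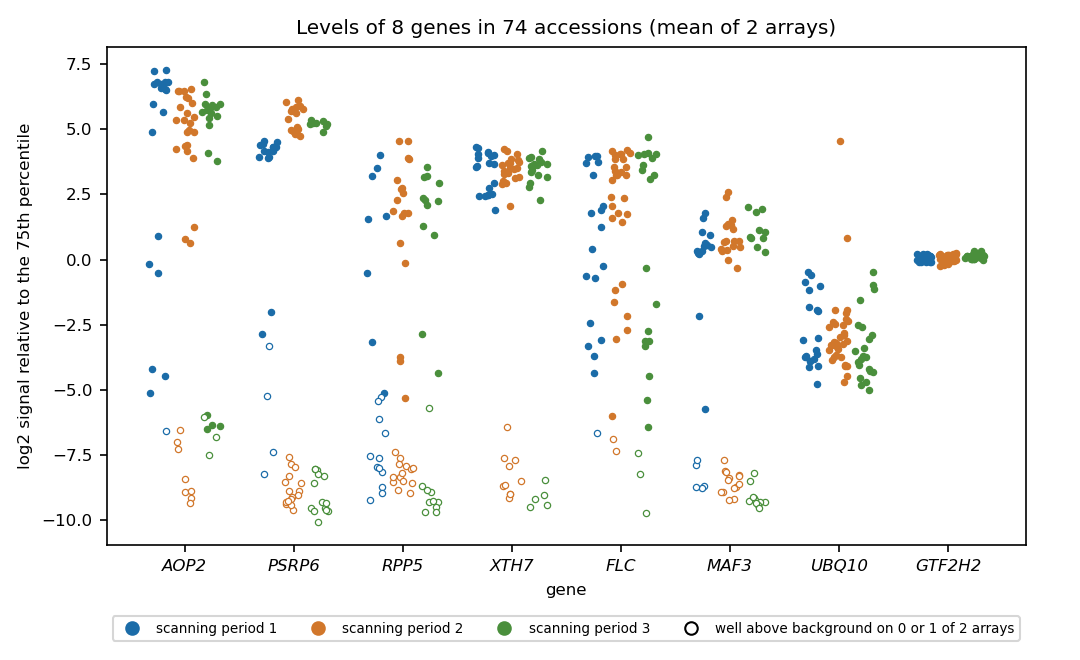
Levels of 8 named genes in 74 accessions (vertical axis, log2 signal relative to the array's 75th percentile, mean of 2 arrays), coloured by scanning period, with open points where fewer than 2 arrays were well above background. *AOP2*, *PSRP6*, *RPP5*, *XTH7*, *FLC* and *MAF3* span from bright to undetected, while the reference gene *UBQ10* spans 746.6-fold, with CS22756 far above the others, and *GTF2H2* 1.47-fold.

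Of the 21887 genes tested, 21805 passed the F-test over the 74 accessions after Benjamini-Hochberg adjustment. A stricter rule, fixed with the test, also asked for a repeatability of at least 0.5 and a span of at least 2 on the log2 scale between the highest and lowest accession mean, and 13802 genes met it. The median SD of accession means was 0.58 and the median replicate SD 0.18. With the slide as a fixed block 21327 genes passed the F-test and 8435 met the strict rule, with the scanning period as a block 21691 and 11900. Under a block the span covers only deviations within slides or periods, which makes the strict rule harder to meet here and in the lists below. The fall in these counts therefore does not measure a slide effect. Within periods 1, 2 and 3 alone 19834, 21475 and 21033 genes passed the F-test and 7726, 10595 and 8415 met the strict rule. A 60-base probe also loses signal where an accession's sequence differs from the probe, and the arrays do not separate that from a lower transcript level.

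The sORFs that were detected differed among accessions too. NEW_TU_6019 (chromosome 5, 4791537 to 4791635, plus strand) reached 7.10 ± 0.12 in CS22635, at least 18580-fold above CS22747, and was detected on both arrays of 66 accessions and on neither array of 6. NEW_TU_721 (chromosome 2, 6567319 to 6567582) and NEW_TU_966 (chromosome 2, 6571604 to 6571756) were both highest in CS22636, at least 2535- and 3708-fold above their lowest accession, and the probe of NEW_TU_966 carries a note of possible cross-hybridisation in the array files. NEW_TU_4502 (chromosome 1, 23506561 to 23506743), NEW_TU_5906 (chromosome 5, 15546362 to 15546496) and NEW_TU_4176 (chromosome 1, 13127387 to 13127557) differed by at least 1181-, 2338- and 657-fold, and they were undetected on both arrays of 54, 43 and 46 accessions. Nothing beyond the coordinates was given for these reading frames in the sources used here. Of 1529 sORFs tested, 1482 passed the F-test and 1038 met the strict rule, with a median repeatability of 0.630 against 0.881 for genes. With the slide as a block 1204 passed and 726 met the strict rule, and with the period as a block 1421 and 874. Where all signals under a common floor were set to that floor, which removes differences between arrays in how far a dim spot can fall, 698 sORFs passed and 329 met the strict rule.

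At matched signal, the difference between the classes in the share of strongly varying features did not pass its test in the main fit. The strict rule was met by 67.9% of tested sORFs and 63.1% of tested genes. At the mean signal of the sORFs a share of 69.7% would have been reached by class labels drawn at random, so the matched difference of sORFs minus genes was -1.84 percentage points (permutation test, two-sided, p = 0.0527, class labels permuted within 20 bins of mean signal). Features are not independent replicates. This difference turned positive with the common floor (3.92 points, p = 1e-05, the smallest the permutations can give) and was -6.10 points with the slide as a block (p = 1e-05), and it was 3.21 points in period 2 alone (p = 0.00209), so no direction is given.

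A group of genes was detected in some accessions and undetected in others. *SYTA* (AT2G20990), a synaptotagmin of the plasma membrane, was well above background on both arrays of 70 accessions (mean 3.26, SD 1.05) and on neither array of 4, a difference of at least 1297-fold. *UGT87A2* (AT2G30140), a UDP-glycosyltransferase, was detected in 65 accessions and undetected in 8 (at least 890.2-fold), and *FKBP15-2* (AT5G48580), a peptidyl-prolyl isomerase of the FKBP family, in 62 and 12 (at least 649-fold). *PSRP6* was detected in 40 accessions and undetected in 31 (at least 2784-fold), *TIR* in 59 and 9 (at least 2196-fold), *AOP2* in 62 and 6 (at least 1704-fold), *XTH7* in 59 and 15 (at least 1303-fold) and *RLM3* in 55 and 17 (at least 541-fold). These bounds use the means of all detected and all undetected accessions. In all 580 genes, 173 of them with a gene symbol, and 70 sORFs met the rule of at least 4 accessions on either side and a bound of at least 8-fold, which is a description and carries no test. Between 86 and 263 of the 580 genes were undetected per accession, with medians of 177.5, 198 and 181.5 in the 3 periods. A note of possible cross-hybridisation goes with 3.97% of their probes, against 1.70% of the genes tested.

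Neighbouring genes could share their state, as in the first of these pairs, which were all chosen after the values were seen. *PSRP6* and *CSA1*, 737 bases apart on chromosome 5, were both detected in 38 accessions, both undetected in 31 and split in 1 (Fisher's exact test, two-sided, p = 4.48e-19, 4 accessions left out because 1 array disagreed). *AOP2* and *AOP3*, 5853 bases apart on chromosome 4, were both detected in 10 accessions, *AOP2* alone in 51, *AOP3* alone in 1 and neither in 5 (Fisher's exact test, p = 1). *RPP4* and *RPP5*, NLR receptors of the same cluster 43310 bases apart, were both detected in 20 accessions, *RPP4* alone in 15, *RPP5* alone in 16 and neither in 13 (Fisher's exact test, p = 1). For *RLM3* with *RPP5* and with *RPP4* Fisher's exact test gave p = 0.392 and 0.410.

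Over the 580 genes, 5 pairs of accessions had nearly the same state. CS22680 and CS22693 differed at 24 to 71 genes between their arrays, CS22695 and CS22574 at 33 to 41, CS22677 and CS22591 at 37 to 55, CS22690 and CS22652 at 53 to 59, and CS6824 and CS6839 at 71 to 79. Replicates of an accession differed at a median of 22 genes and at most 91, and arrays of all other accessions at a median of 180 and at least 98. The correlations of accession means in the 5 pairs ran from 0.975 to 0.983 across probes, against a median of 0.936 over all pairs. The limit for a similar pair was the highest number between replicates and was set after the values were seen, and the stock codes do not tell how the lines are related.

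**Figure D3:**
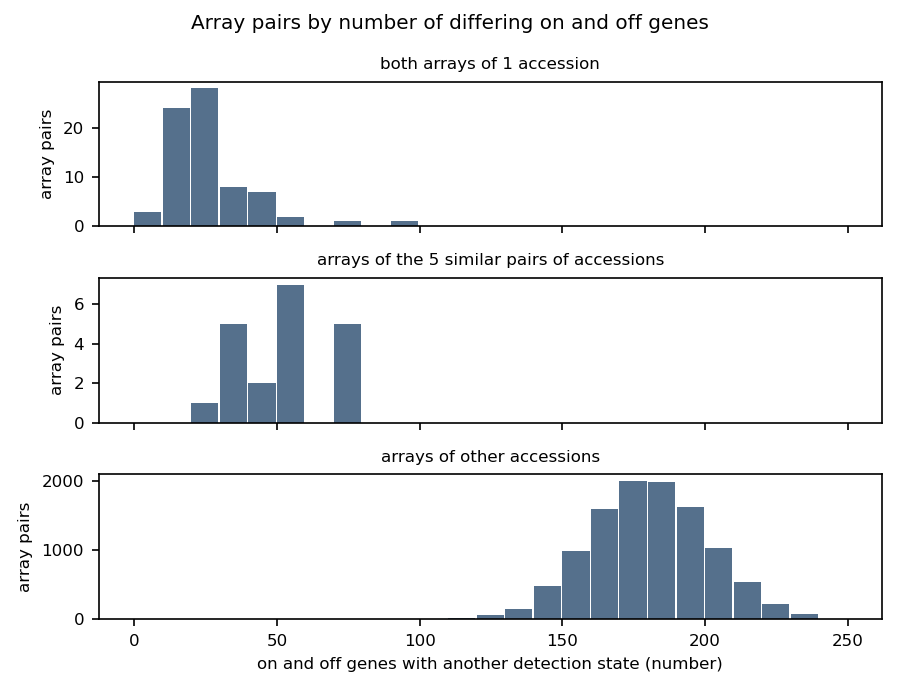
Number of array pairs (vertical axis) by the number of on and off genes at which their detection state differs (horizontal axis, of 580), for replicates of an accession, arrays of the 5 similar pairs and arrays of other accessions. The arrays of similar pairs differ at 24 to 79 genes and overlap the replicates (median 22), while those of other accessions differ at 98 or more.

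The 16 gene lists fixed before the data were examined held 302 genes, of which 270 could be tested. Of the others, 10 were not well above background on both arrays of any accession, 21 had a symbol that the reference table did not pair with the locus, and 1 had no probe of its own. A list's score is the mean z-score of its members on an array. The accessions differed in the score of each of the 16 lists (permutation test of F, p = 1e-05 for each and adjusted p = 1e-05, the smallest these permutations can give). Of all genes tested 99.6% passed the F-test, so neither this nor the members passing below sets a list apart. With the slide as a block and arrays permuted within slides p was 5e-05 for 15 lists (adjusted p = 5.33e-05), the smallest that 20000 permutations can give, and 1e-04 for root markers.

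Genes that make and break down glucosinolates, the sulphur compounds that deter herbivores, varied widely. Beside *AOP2*, the hydroxyalkyl-forming *AOP3* (AT4G03050) reached 2.30 ± 0.04 in CS22686, at least 837-fold above CS6824. The myrosinase *TGG2* (AT5G25980) was measured in all 74 accessions and differed 709-fold between CS22643 (6.04 ± 0.06) and CS22591 (-3.43 ± 0.10). *CYP79F1* (AT1G16410), which oxidises chain-elongated methionine, was detected on both arrays of 20 accessions and differed by at least 44.9-fold, and the sulfotransferase *SOT16* (AT1G74100), the least variable member, by 3.05-fold. All 31 members tested passed the F-test among all genes and when adjusted over the list alone, 30 met the strict rule, and with the slide as a block 31 passed and 25 met it. The median SD of the members' accession means was 1.05, above that of each of 10000 random lists of matched signal (median 0.46). The score was highest in CS22686 (0.77 ± 0.02) and lowest in CS22615 (-1.36 ± 0.15). It averaged 0.246 ± 0.315 (SD, n = 20), -0.175 ± 0.595 (n = 32) and 0.0310 ± 0.297 (n = 22) over the accessions of the 3 periods (permutation test, adjusted p = 0.0112 over 16 lists). The score of root markers moved with it over accessions (r = 0.466, permutation p = 1e-05, within periods r = 0.426, adjusted p = 0.00211 over 39 such relations). Most root markers were not detected on both arrays of every accession. None of the relations with marker lists, here and below, was run with the common floor.

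Genes of flowering time differed over a wide range. *FLC* (AT5G10140), the repressor of flowering, reached 4.70 ± 0.05 in CS6857, at least 4436-fold above CS6824, and its relatives *MAF3* (AT5G65060) and *MAF4* (AT5G65070) varied with SDs of 4.78 and 1.84. *MAF3* was undetected on both arrays of 31 accessions and at least 1330-fold higher in CS22567 than in CS917. *SOC1* (*AGL20*, AT2G45660), which promotes flowering and is repressed by FLC, was detected in every accession and differed 181-fold between CS22626 (4.44 ± 0.06) and CS22807 (-3.06 ± 0.10). The least variable member, *SPL5* (AT3G15270), a target of microRNA 156 in the ageing pathway, still differed 12.9-fold. All 19 members tested passed, also when adjusted over the list alone, 18 met the strict rule, and with the slide as a block 19 passed and 18 met it. The median repeatability of the members was 0.959, above each of 10000 random lists (median 0.870). The score averaged 0.202 ± 0.361, -0.0591 ± 0.269 and -0.0973 ± 0.192 in periods 1, 2 and 3 (adjusted p = 0.00188), and the score of floral organ markers rose with it over accessions (r = 0.589, permutation p = 1e-05, within periods 0.563, adjusted p = 0.000195).

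Clock genes had the highest median repeatability of the lists without a block, and with the slide as a block 0.946 against 0.972 for NLR immune receptors and 0.954 for flowering time. *COR27* (AT5G42900), a cold-regulated gene that acts in the clock, was at least 1305-fold higher in CS22689 than in CS22754. *ELF4* (AT2G40080), a part of the evening complex, differed 1349-fold between CS22692 (5.20 ± 0.10) and CS22698 (-5.20 ± 0.05), and the blue-light receptor *FKF1* (AT1G68050) differed 530-fold between CS22693 and CS22712. The morning gene *LHY* (AT1G01060) differed 172-fold in the other direction, with 2.66 ± 0.27 in CS22712 and -4.76 ± 0.31 in CS22689, while *ZTL* (AT5G57360), another light receptor of the clock, differed 3.37-fold. All 18 members tested passed, also when adjusted over the list alone, and 17 met the strict rule (18 and 15 with the slide as a block). The median repeatability was 0.971, above each of 10000 random lists (median 0.898). Mean levels of *FKF1* were -0.01, -2.81 and -0.27 in the 3 periods and those of *LHY* -1.76, 0.41 and -1.06. The hour of harvest is not given in the sources used here. Differences between accessions in clock genes are therefore not told apart from differences in the hour of collection, also within a period. This limit holds as well for the relations with clock genes below. The list joins genes of opposite phase, and its score averaged -0.104 ± 0.220, -0.0170 ± 0.241 and 0.119 ± 0.194 (adjusted p = 0.0112). The root marker score moved against it (r = -0.551, permutation p = 1e-05, within periods -0.474, adjusted p = 0.00026).

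Cold and drought genes differed strongly between periods as well as accessions. *COR15A* (AT2G42540), which protects chloroplast membranes in the cold, differed 484-fold between CS6902 (4.57 ± 0.12) and CS22712 (-4.34 ± 0.11). The cold transcription factors *DREB1A* (AT4G25480) and *CBF1* (AT4G25490) were highest in CS6918, at least 609- and 95.2-fold above their lowest accession, and *GolS2* (AT1G56600), which makes galactinol under drought, was at least 115-fold higher in CS22687 than in CS22634. *COR413-PM1* (AT2G15970), a cold-regulated membrane protein and the least variable member, differed 9.19-fold. All 17 members passed, also when adjusted over the list alone, and all met the strict rule (17 and 16 with the slide as a block). The score averaged 0.297 ± 0.544, -0.513 ± 0.398 and 0.475 ± 0.546 in periods 1, 2 and 3, and 47.4% of the variance of accession scores lay between periods (adjusted p = 4e-05).

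Defence genes of the salicylic acid pathway varied widely between accessions and also between replicates. *PR1* (AT2G14610), its classic marker, was 5.12 ± 0.74 in CS6706, at least 2389-fold above CS22626, with a replicate SD of 1.66. *AIG1* (AT1G33960), induced by bacterial infection, reached 2.71 in CS22638, at least 1443-fold above CS917. *FMO1* (AT1G19250) and *ALD1* (AT2G13810), enzymes of the systemic signal N-hydroxypipecolic acid, differed by at least 243- and 65.5-fold with replicate SDs of 1.65 and 1.75, and *SID2* (*EDS16*, AT1G74710), the isochorismate synthase that makes salicylic acid, by 4.87-fold. All 19 members tested passed, also when adjusted over the list alone, and met the strict rule (19 and 17 with the slide as a block), yet their median repeatability of 0.814 lay at percentile 0.03 of random lists (0.805 and percentile 28.0 with the slide as a block). The score was highest in CS22765 (1.25 ± 0.30) and lowest in CS22698 (-1.35 ± 0.13) and averaged 0.0610 ± 0.511, -0.0395 ± 0.618 and 0.00198 ± 0.520 in the 3 periods (adjusted p = 0.822).

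NLR immune receptors were the most variable list. After *RPP5*, *RPP4* (AT4G16860), of the same downy mildew resistance cluster, reached 3.90 ± 0.09 in CS6918, at least 3281-fold above CS917. *RPM1* (AT3G07040), a receptor for bacterial effectors, differed by at least 247-fold and was undetected on both arrays of 10 accessions, while *ZAR1* (AT3G50950) was detected throughout and differed 3.88-fold. All 16 members tested passed, also when adjusted over the list alone, and 15 met the strict rule (16 and 14 with the slide as a block). The median SD was 1.83, the highest of the 16 lists, against 0.51 for random lists. Those lists were matched on signal and not on sequence differences under the probes. Such differences also lower the signal, so this spread is not one of transcript levels alone for certain. The lowest score was that of CS22682 (-1.65 ± 0.13), and scores averaged -0.0931 ± 0.503, 0.0512 ± 0.339 and 0.0110 ± 0.259 in the 3 periods (adjusted p = 0.429).

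Jasmonate and ethylene defence genes all varied strongly. The defensins *PDF1.2c* (AT5G44430) and *PDF1.3* (AT2G26010) were highest in CS6857, at least 11134- and 3440-fold above their lowest accession, and the probe of *PDF1.2c* carries a note of possible cross-hybridisation. The arginase *ARGAH2* (AT4G08870) reached 6.42 ± 0.39 in CS22574, at least 13673-fold above CS6706, and the storage protein *VSP1* (AT5G24780) was at least 588-fold higher in CS22695 than in CS6824. *AOS* (AT5G42650), the allene oxide synthase of jasmonate synthesis, differed 8.17-fold. All 19 members passed, also when adjusted over the list alone, and met the strict rule, with and without the slide as a block. Scores averaged -0.0767 ± 0.491, -0.0528 ± 0.535 and 0.146 ± 0.487 in the 3 periods (adjusted p = 0.341). Within periods the score rose with that of root markers (r = 0.399, adjusted p = 0.00267) and fell with that of floral organ markers (r = -0.294, adjusted p = 0.0407).

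Anthocyanin genes had their highest mean score in CS22574, where the arrays lay far apart (0.899 and 2.098). Its first array lay below both arrays of CS22695 (1.42 and 1.303), so this rank rests on the second. *DFR* (AT5G42800) and *LDOX* (AT4G22880), successive enzymes on the way to anthocyanidins, were 0.41 ± 1.79 and 1.095 ± 1.49 there, at least 167- and 228-fold above CS22703. The glycosyltransferase *UF3GT* (AT5G54060) was at least 99.9-fold higher in CS22574 than in CS22682, and *PAP1* (AT1G56650), the MYB factor that turns the pathway on, had an SD of accession means of 1.45. *UGT78D2* (AT5G17050), which glycosylates flavonoids at position 3, differed 4.97-fold. All 19 members tested passed, also when adjusted over the list alone, and 18 met the strict rule (19 and 16 with the slide as a block). The score was 1.50 ± 0.85 in CS22574 and averaged 0.00192 ± 0.697, -0.0929 ± 0.611 and 0.133 ± 0.392 in the 3 periods (adjusted p = 0.429). The root marker score rose with it (r = 0.474, permutation p = 5e-05, within periods 0.614, adjusted p = 0.000195).

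Photosynthesis genes differed between scanning periods more than any other list. *CAB1* (AT1G29930), a light-harvesting protein of photosystem II, averaged 7.74, 9.19 and 8.46 in periods 1, 2 and 3, and with the slide as a block it did not pass (adjusted p = 0.781). *LHCA1* (AT3G54890), of the antenna of photosystem I, differed 40.5-fold between CS6907 (8.75 ± 0.01) and CS6897 (3.41 ± 0.07). *LHCB2.2* (AT2G05070) and *CAB2* (AT1G29920), further light-harvesting genes, differed by at least 194- and 288-fold, *LHCB2.2* being undetected on both arrays of 14 accessions, and *LHCB5* (AT4G10340) by 2.48-fold. All 23 members tested passed, also when adjusted over the list alone, and 19 met the strict rule. With the slide as a block 14 passed (13 when adjusted over the list alone) and 4 met it, and the median repeatability of the members was then at percentile 0.02 of random lists. The score averaged -0.969 ± 0.353 (SD, n = 20), 0.606 ± 0.466 (n = 32) and 0.000514 ± 0.297 (n = 22), and 73.6% of the variance of accession scores lay between periods (adjusted p = 4e-05). The root marker score moved against it in the pooled accessions (r = -0.460, permutation p = 3e-05) and not within periods (r = -0.222, adjusted p = 0.184). Other bright genes of matched signal also differed between periods 1 and 2, by a median of 0.475 against 1.16 for the list. With quantile normalization these values were 0.0105 and 0.330, so the size of the difference depends on the scaling, and the hour of harvest is not given in the sources used here.

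Genes of iron and copper status followed. *CCS* (AT1G12520), the chaperone that loads copper into superoxide dismutase, was at least 2339-fold higher in CS22636 (3.81 ± 0.08) than in CS6891 and undetected on both arrays of 18 accessions. The iron-deficiency factors *BHLH100* (AT2G41240), *bHLH39* (AT3G56980) and *bHLH38* (AT3G56970) were each highest in CS22602, at least 6951-, 2650- and 1011-fold above their lowest accession. *FSD1* (AT4G25100), an iron superoxide dismutase, differed 7.16-fold. All 13 members tested passed, also when adjusted over the list alone, and met the strict rule (13 and 10 with the slide as a block). Scores averaged -0.319 ± 0.395, 0.233 ± 0.554 and -0.0489 ± 0.428 in the 3 periods (adjusted p = 0.00178). The senescence score moved against this list (r = -0.305, permutation p = 0.0082, within periods -0.468, adjusted p = 0.00039).

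Known small peptides varied about as much as other genes of their signal. *PSK5* (AT5G65870), a precursor of the growth peptide phytosulfokine, differed 47.1-fold between CS22626 (1.63 ± 0.10) and CS22607 (-3.93 ± 0.18), and *PSK2* (AT2G22860), another precursor, by at least 34.1-fold. *RCI2A* (AT3G05880), a small membrane protein induced by cold, differed 16.4-fold, *PROPEP2* (AT5G64890), a precursor of a danger signal, at least 7.78-fold, and *BRK1* (AT2G22640), a subunit of the actin-regulating SCAR complex, 2.15-fold. *PROPEP2* was detected on both arrays of 12 accessions and lost its call with the common floor (adjusted p = 0.604). All 21 members tested passed, also when adjusted over the list alone, and 19 met the strict rule (21 and 14 with the slide as a block). The median SD of 0.78 lay at percentile 71.8 of random lists. Scores averaged 0.103 ± 0.299, -0.171 ± 0.313 and 0.155 ± 0.239 in the 3 periods (adjusted p = 0.000453). The senescence score rose with it (r = 0.296, permutation p = 0.01, within periods 0.394, adjusted p = 0.00329).

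Subunits of the 20S proteasome, the proteolytic core particle, varied least. *PBF1* (AT3G60820) differed 1.79-fold between its highest and lowest accession, *PBG1* (AT1G56450) 2.92-fold, *PAC1* (AT3G22110) 3.06-fold and *PAF1* (AT5G42790) 11.3-fold. *PBB1* (AT3G27430) stood apart: its probe was detected on both arrays of 14 accessions, undetected on both arrays of 58 and at least 77.3-fold higher in CS22676 than in CS6824. With 1 probe per gene, loss of signal at the probe is not told apart from a lower transcript level. All 14 members passed, also when adjusted over the list alone, and 2 met the strict rule (13 and 2 with the slide as a block). The median SD of 0.28 was at percentile 0.1 of random lists (median 0.42). Scores averaged -0.444 ± 0.369, 0.145 ± 0.278 and 0.193 ± 0.230 in the 3 periods (adjusted p = 4e-05), and the root marker score moved against them pooled (r = -0.369, permutation p = 0.0012) and not within periods (r = 0.0125, adjusted p = 0.938).

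Genes in common use as references for quantification differed in signal among accessions as well. Each had 1 probe, and the arrays do not separate loss of signal at the probe from a lower transcript level. The polyubiquitin gene *UBQ10* (AT4G05320) differed 746.6-fold between CS22756 (4.55 ± 0.02) and CS6889 (-4.99 ± 0.02), and *PEX4* (AT5G25760), a ubiquitin-conjugating enzyme of the peroxisome, 4.03-fold. *UBQ10* was 0.81 in CS22615 and at most -0.465 in all others, so the upper end of its span rests on CS22756. *GAPC1* (AT3G04120), the cytosolic glyceraldehyde phosphate dehydrogenase, was undetected on both arrays of 33 accessions, differed by at least 6.20-fold and lost its call with the common floor (adjusted p = 0.563). The ubiquitin-conjugating *UBC9* (AT4G27960) was -7.63 ± 1.17 in CS22686, where 1 of 2 arrays was not well above background, and 0.29 ± 0.07 in CS6769. *PP2AA3* (AT1G13320), a subunit of protein phosphatase 2A, was the least variable (1.70-fold). All 9 members tested passed, also when adjusted over the list alone, and 4 met the strict rule (9 and 3 with the slide as a block). Scores averaged 0.113 ± 0.329, 0.135 ± 0.369 and -0.299 ± 0.255 in the 3 periods (adjusted p = 6.4e-05). Within periods the score moved against that of root markers (r = -0.308, adjusted p = 0.0407).

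**Figure D4:**
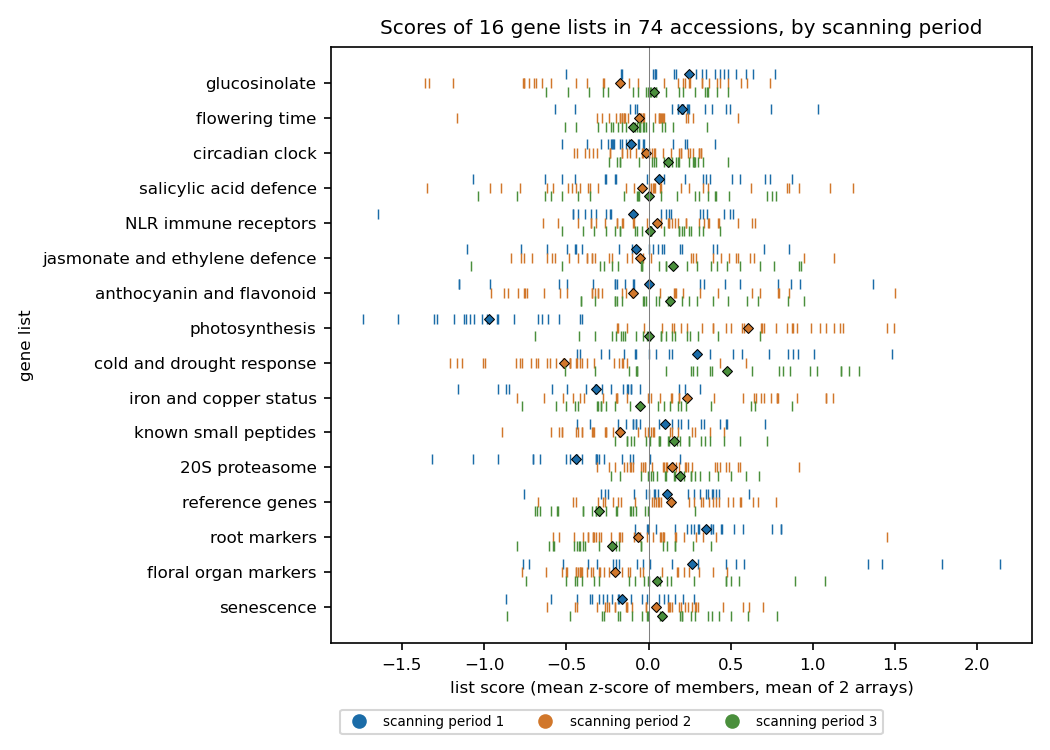
Scores of the 16 gene lists (horizontal axis, mean z-score of the members, mean of 2 arrays) with 1 tick per accession coloured by scanning period and a diamond at the mean of each period. Photosynthesis scores averaged -0.969 in period 1 and 0.606 in period 2, and cold and drought scores -0.513 in period 2 and 0.475 in period 3.

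Markers of other organs and stages that aerial parts could hold were measured beside these lists. Among root markers, the nitrate transporter *NRT2:1* (AT1G08090) was detected on both arrays of 31 accessions and at least 34.3-fold higher in CS22695 than in CS6736. The iron transporter *IRT1* (AT4G19690), the thalianol synthase *THAS1* (AT5G48010) and the auxin carrier *EIR1* (AT5G57090) were detected in 5, 19 and 7 accessions and differed by at least 32.2-, 8.62- and 9.92-fold, *THAS1* losing its call with the common floor. *LRX1* (AT1G12040), a cell wall protein known from root hairs, was detected in all 74 accessions and differed 4.99-fold. Of 11 root markers tested 11 passed, also when adjusted over the list alone, and 10 met the strict rule (10 and 8 with the slide as a block). The score was highest in CS22574 (1.45 ± 0.39) and averaged 0.349 ± 0.259, -0.0650 ± 0.381 and -0.223 ± 0.320 in the 3 periods (adjusted p = 4e-05). Of these 11 genes, 4 were detected on both arrays of every accession.

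Floral organ markers were highest in CS22687 (score 2.14 ± 0.33). There *AP1* (AT1G69120), a gene of floral meristems, was -0.23 ± 0.56, at least 113-fold above CS6857, and the carpel gene *CRC* (AT1G69180) at least 50.6-fold above CS6824. *SEP3* (AT1G24260), a floral organ identity gene detected in all accessions, differed 127-fold between CS6826 and CS22616, and *SEP1* (AT5G15800) by at least 28.1-fold. *STK* (AT4G09960), an ovule gene detected on both arrays of 1 accession, did not pass (adjusted p = 0.134, with the slide as a block 0.0374). Of 10 markers tested 9 passed, also when adjusted over the list alone, and 9 met the strict rule (10 and 8 with the slide as a block). Scores averaged 0.266 ± 0.822, -0.202 ± 0.316 and 0.0530 ± 0.467 in the 3 periods (adjusted p = 0.0148). Of the 10 genes 1 was detected on both arrays of every accession.

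Senescence genes varied more than random genes of their signal. The asparagine synthetase *ASN1* (AT3G47340), induced by darkness, differed 439-fold between CS22683 (7.04 ± 0.09) and CS6674 (-1.74 ± 0.06), and *SAG13* (AT2G29350), a senescence-associated gene, 216-fold. The ribonuclease *RNS1* (AT2G02990) and the sugar transporter *SAG29* (AT5G13170) differed by at least 137- and 223-fold, and *ATG8H* (AT3G06420), of the autophagy machinery, by 5.25-fold. All 11 members tested passed, also when adjusted over the list alone, and met the strict rule (11 and 8 with the slide as a block). The median SD of 1.03 lay at percentile 99.9 of random lists. Scores averaged -0.162 ± 0.285, 0.0432 ± 0.317 and 0.0846 ± 0.378 in the 3 periods (adjusted p = 0.0492). Of the 11 genes 8 were detected on both arrays of every accession.

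Of 15 relations between genes or lists with a textbook link, chosen before the data were examined, 11 had an adjusted p under the threshold over the 74 accessions. *FLC* and *SOC1* moved in opposite directions (Pearson r = -0.731, Spearman rho = -0.813, without the 2 accessions farthest from the median of *FLC* r = -0.750) and so did *FLC* and *FT*, the mobile signal of flowering (-0.635, -0.685 and -0.654). *FT* rose with *FUL* (*AGL8*), a gene of the floral transition (0.696, 0.649 and 0.673). The clock genes *CCA1*, of the morning, and *TOC1*, of the evening, were opposed (-0.864, -0.856 and -0.851). In the anthocyanin pathway *DFR* rose with its regulators *TT8*, a bHLH factor (0.780, 0.723 and 0.735), and *PAP1* (0.513, 0.534 and 0.519), and the scores of salicylic acid and jasmonate defence rose together (0.526, 0.490 and 0.499). For these 7 relations the permutation p of r, of rho and of r within periods was 1e-05 each, the smallest possible (adjusted 2.14e-05 over 15). Within periods r was -0.721, -0.613, 0.662, -0.869, 0.781, 0.567 and 0.538 in the order given. In periods 1, 2 and 3 r was -0.750, -0.737 and -0.762 for *FLC* with *SOC1*, -0.732, -0.443 and -0.668 for *FLC* with *FT*, and 0.806, 0.241 and 0.918 for *FT* with *FUL*. It was -0.891, -0.772 and -0.923 for *CCA1* with *TOC1*, 0.803, 0.808 and 0.636 for *TT8* with *DFR*, 0.664, 0.519 and 0.513 for *PAP1* with *DFR*, and 0.423, 0.594 and 0.535 for the defence scores. *FT* was undetected on both arrays of 51 accessions, and with the common floor its r with *FLC* was -0.325 and with *FUL* 0.422.

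**Figure D5:**
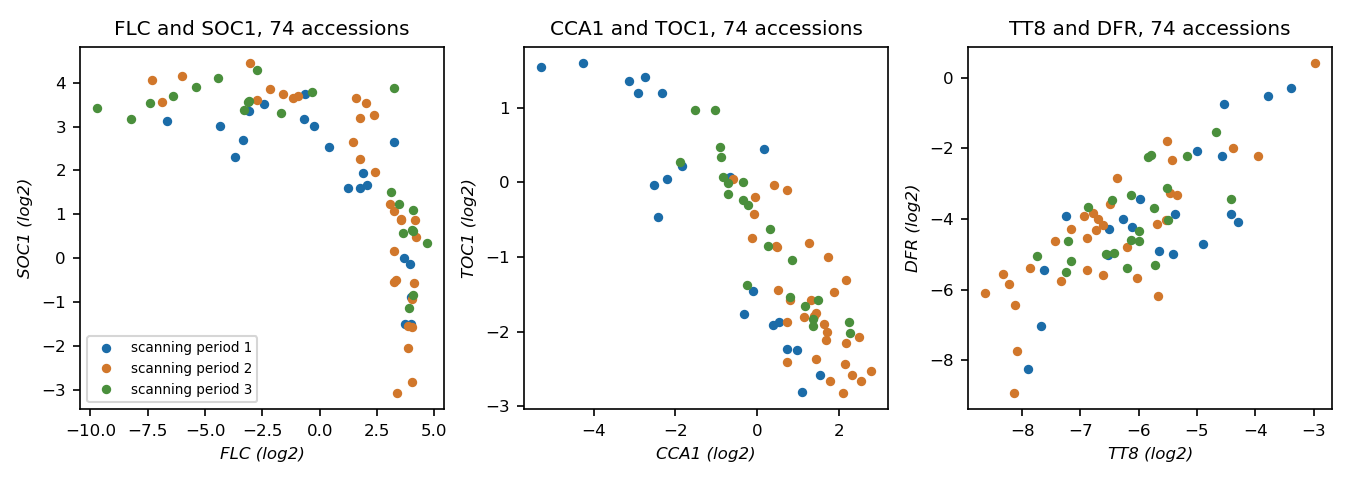
Levels of 3 pairs of genes in 74 accessions (log2 signal relative to the array's 75th percentile, mean of 2 arrays on both axes), 1 point per accession coloured by scanning period. *SOC1* falls with *FLC* (r = -0.731), *TOC1* falls with *CCA1* (r = -0.864) and *DFR* rises with *TT8* (r = 0.780).

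The other relations were weaker. Scores of circadian clock and of cold and drought genes rose together (r = 0.357, permutation p = 0.00188, adjusted 0.00353, rho = 0.307, p = 0.00815, adjusted 0.0153, without 2 accessions 0.335), with r = 0.669, 0.0363 and 0.684 in periods 1, 2 and 3 and 0.410 within periods (adjusted p = 0.0005). Salicylic acid and photosynthesis scores were opposed (r = -0.299, permutation p = 0.00985, adjusted 0.0164, rho = -0.296, p = 0.0111, adjusted 0.0185, without 2 accessions -0.304, within periods -0.460, adjusted p = 0.000225). For these scores r was -0.472, -0.562 and -0.179 in periods 1, 2 and 3, and with normexp and quantile normalization (r = -0.235) the relation did not pass. The cold factor *CBF2* (AT4G25470) rose with its target *COR15A* (r = 0.280, permutation p = 0.0151, adjusted 0.0227, rho = 0.273, p = 0.0188, adjusted 0.0256, without 2 accessions 0.350), but within periods this did not hold (r = 0.209, adjusted p = 0.0923). *PAD4* (AT3G52430), a regulator of salicylic acid signalling, rose with *PR1* (r = 0.243, permutation p = 0.0364, adjusted 0.0496, rho = 0.279, p = 0.0156, adjusted 0.0234, without 2 accessions 0.200, within periods 0.303, adjusted p = 0.0153). For *PAD4* and *PR1* r was 0.153, 0.201 and 0.635 in periods 1, 2 and 3, and with the common floor (r = 0.240) the relation did not pass. No relation passed for *SID2* and *PR1* (r = 0.114, permutation p = 0.337, adjusted 0.389, rho = 0.0780, p = 0.507, adjusted 0.543, without 2 accessions 0.0473, within periods 0.199). The same held for *ACD6* (AT4G14400), an ankyrin protein that activates defence, and *PR1* (r = 0.127, permutation p = 0.28, adjusted 0.35, rho = 0.142, p = 0.227, adjusted 0.284, without 2 accessions 0.129, within periods 0.129). It held for *MYB28* (AT5G61420), a regulator of aliphatic glucosinolates, and *CYP79F1*, which most accessions did not have detected on both arrays (r = 0.102, permutation p = 0.386, adjusted 0.414, rho = 0.00108, p = 0.993, adjusted 0.993, without 2 accessions 0.0807, within periods 0.0798). It held too for anthocyanin and photosynthesis scores (r = -0.0629, permutation p = 0.596, adjusted 0.596, rho = -0.108, p = 0.359, adjusted 0.414, without 2 accessions -0.00504, within periods -0.0110).

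Each accession was also set against the mean of the other 73. The SE and p of such a contrast rest on the spread between replicates, not on the spread among the other accessions. They do not measure how unusual an accession is: for *PSRP6* in CS6907 the SE was 0.65 and the SD of the others 6.75. CS22682 had the most genes apart, 4957 beyond a difference of 1 on the log2 scale at an adjusted p under the threshold, 2833 higher and 2124 lower. With the period as a block it had 1516 higher and 1719 lower, and with normexp and quantile normalization 1075 and 1157, so neither the total nor the excess of higher genes was stable. Its histone acetyltransferase gene *HAM2* (AT5G09740) was undetected on both arrays, at least 351-fold below the other 73 accessions, each of which had it detected on both arrays (measured difference -10.55 ± 0.07, SE). The NLR gene *RPP8* (AT5G43470) and *FKBP15-2* were undetected there too, at least 305- and 721-fold below the 70 and 62 accessions that had them detected on both arrays. Higher than the mean of the others were *AGD6* (AT3G53710), an activating protein of ARF GTPases, by 7.32 ± 0.56 (SE), *CRU3* (AT4G28520), a cruciferin storage protein of seeds, by 6.505 ± 1.11, and *HISN5B* (AT4G14910), of histidine synthesis, by 6.26 ± 0.24. These 3 genes were undetected on both arrays of 52, 58 and 50 of the other accessions, so the differences rest in part on signals near background. They were detected on both arrays of 18, 3 and 23 others, and CS22682 ranked 3, 2 and 16 from the top. Detection of *HISN5B* therefore does not set CS22682 apart. CS22692 followed with 4708 genes. Its zinc finger gene *ZAT11* (AT2G37430), the phospholipase gene AT4G16820 and the methyltransferase gene *FAMT* (AT3G44860) were higher by 7.93 ± 0.67, 7.93 ± 0.80 and 7.59 ± 0.56 (SE), with 33, 31 and 24 others undetected. *EMB2786* (AT3G17300), named for an embryo-defective mutant, and the helper NLR *ADR1* (AT1G33560) were undetected, at least 118- and 92.3-fold below the 72 and 71 accessions that had them detected, and *SYTA* was measured on both arrays at -4.83 against 2.71 in the others (difference -7.53 ± 0.18, SE).

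CS22685 had 4597 genes apart. *AGD6* and *HISN5B* were higher there too, by 7.65 ± 0.56 and 5.88 ± 0.24 (SE), with *SR34b* (AT4G02430), a splicing factor, by 5.92 ± 0.52, undetected in 42 others. CS22685 ranked 2, 23 and 13 from the top for *AGD6*, *HISN5B* and *SR34b*. These genes were detected on both arrays of 18, 23 and 24 others, so detection of the last 2 does not set CS22685 apart. *FKBP15-2* was at least 477-fold below the 62 accessions that had it detected, while *CRL1* (AT2G33590), related to cinnamoyl-CoA reductase, and *TIR* were measured on 1 of 2 arrays, with differences of -9.22 ± 0.12 and -9.16 ± 0.67 (SE). CS22685 ranked lowest for *CRL1* but 12 from the bottom for *FKBP15-2* and 13 for *TIR*. The latter 2 genes were undetected on both arrays of 11 and 9 others. In CS6907, with 4575 genes, *PSRP6* was higher by 7.60 ± 0.65, *RPP5* by 7.32 ± 0.78 and *RGTA2* (AT5G41820), an alpha subunit of Rab geranylgeranyl transferase, by 6.75 ± 0.43 (SE), with 31, 31 and 54 others undetected. *BT4* (AT5G67480), of the BTB and TAZ domain family, and the sterol desaturase *CYP710A2* (AT2G34490) were undetected, at least 179- and 163-fold below the other 73, and *MLP43* (AT1G70890), of the major latex protein family, was measured on 1 of 2 arrays (difference -11.06 ± 0.18, SE). In CS22683, with 4539 genes, *RGTA2* and *TSC10B* (AT5G19200), a reductase of sphingolipid synthesis, were higher by 6.35 ± 0.43 and 6.28 ± 0.34 and *PSRP6* by 5.73 ± 0.65 (SE), with 54, 62 and 31 others undetected. CS22683 ranked 4 and 3 from the top for *RGTA2* and *TSC10B* but 32 for *PSRP6*. Of the other 73 accessions 39 had *PSRP6* detected on both arrays, so its detection does not set CS22683 apart. *FKBP15-2* and *LSU2* (AT5G24660), induced by sulphur shortage, were at least 770.2- and 111-fold below the 62 and 69 accessions that had them detected, and the cytochrome P450 gene *CYP71B34* (AT3G26300) was measured on 1 of 2 arrays (difference -10.36 ± 0.18, SE). For genes measured on 1 of 2 arrays the other array was not well above background, so the size of these differences is uncertain.

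Over the 74 accessions the median was 3470.5 genes apart, and the fewest were 1940 in CS6839 and 2339 in CS22643. With the slide as a block an accession is set only against those on its slides, which are 3 in period 1 and 1 in periods 2 and 3, and the median was then 3000. With the period as a block it is set against the others of its period, and the median was 2859. With the common floor it was 1910.5 and with normexp and quantile normalization 1355.5, where the 5 accessions with most genes had 2232, 2381, 2443, 2021 and 2138. The 5 accessions with most genes had 3883, 3035, 3262, 4083 and 3015 with the slide and 3235, 3279, 3024, 3797 and 2471 with the period as a block, in the order described. In fits of their own period alone, they had 3032, 3139, 2904, 3785 and 2228 genes apart. The order of accessions depended on the choice: CS22574 and CS22590, which share a slide, had the most genes apart with the slide as a block (4773), CS6660 with the period as a block (3823) and CS22685 with the common floor. The call of *PSRP6* in CS6907 was lost against the accession on the same slide (adjusted p = 0.733), and its measured difference in CS22683 moved from 5.73 to 2.81 with the period as a block. CS6907 also had 587 sORFs higher than elsewhere, the most of any accession, and 176 against the accession on the same slide, 117 with the common floor and 96 with normexp and quantile normalization. Its arrays were dim, with a 75th percentile of 497 units. Over accessions the number of higher sORFs fell with that percentile (r = -0.675, rho = -0.592, permutation p = 1e-05 for each, without 2 accessions r = -0.680, within periods rho = -0.598), also with the common floor (r = -0.600, rho = -0.501, permutation p = 1e-05 for each).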

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

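The alternative with the common floor was chosen after the result was seen.

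Probes outside the comparison of genes with sORFs varied at least as often as those inside it. Of 1041 tested probes for other transcripts 871 met the strict rule (83.7%), and of 216 tested probes for several features 161 did (74.5%). With the slide as a block 634 and 110 probes met it, and with the common floor 521 and 128. The probes of the second kind all carry a note of cross-hybridisation in the array files, and neither kind is weighed further here.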

How the results depend on the processing

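The common floor, its joint use with the slide block, the period block, single periods, the omission of cross-hybridising probes and that of CS22574 and CS22693 were chosen after the result was seen. The other alternatives were planned.

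Between 14729 and 25486 genes passed the F-test under the alternatives (21805 here), while the number of sORFs (1482) moved farther. It was 4815 without a filter, 473 and 95 with probes well above background on at least 50% and on all of the arrays, 698 with the common floor and 746 with floor and slide block. Period 1 gave 729 and with the floor 388, and periods 2 and 3 with the floor 596 and 445. Leaving out 1 array at a time, for 100 arrays drawn at random, gave 21790 to 21817 genes and 1475 to 1491 sORFs.

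Strongly varying genes (13802) numbered 8615 with normexp and quantile, 7791 with probes detected on all arrays, 8435 with the slide block and 6160 with floor and slide. Period 1 gave 7726 and with the floor 5487, period 2 with the floor 7439, period 3 8415 and with the floor 5516. Strongly varying sORFs (1038) numbered 288 with normexp, 428 and 80 with these filters, 329 with the floor and 269 with floor and slide, and 512, 152, 279 and 172 in period 1, in period 1 with the floor and in periods 2 and 3 with the floor. Smaller groups also leave fewer features to pass, and the cause was not tested.

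The matched difference of sORFs minus genes (-1.84 points) reversed with normexp and quantile (3.19, permutation p = 3e-05), quantile alone (0.368, p = 0.708), probes on 50% (3.19, p = 0.0209) and all of the arrays (19.9, p = 3e-05), the floor (3.92, p = 1e-05) and floor with slide (3.91, p = 1e-05). It also reversed in period 1 with the floor (2.198, permutation p = 6e-05), period 2 (3.21, p = 0.00209) and with the floor (4.998, p = 1e-05), period 3 with the floor (2.85, p = 1e-05) and without bins of signal (4.51, p = 0.0002). It passed as negative without a filter (-2.32, permutation p = 1e-05), with slide (-6.10), scan day (-6.00, p = 1e-05) and period blocks (-2.33, p = 0.0222), without cross-hybridising probes (-4.30, p = 0.0001), in periods 1 (-4.65) and 3 (-6.06, p = 1e-05) and with the F-test alone (-0.860, p = 0.00792). No direction is claimed, and the cause was not tested.

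Over all accessions, replicate numbers shared little (median r of replicate differences 0.0179 over 2701 pairs, 863 above 0.1 and 722 under -0.1). In period 1, where the first and second replicates of each accession lay on different slides and days, the median was 0.147 and 60% of pairs lay above 0.1, so replicates pair there in part. Period 1 alone was not run with a replicate block. With a replicate block 21804 genes and 1486 sORFs passed, the class difference was -1.52 (permutation p = 0.112) and the median of genes apart 3474.5.

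The median number of genes apart in an accession (3470.5) was 1355.5 with normexp and quantile, 1057.5 with probes on all arrays, 1910.5 with the floor, 1986.5 with floor and slide, and 1645, 1861.5 and 1506.5 in periods 1, 2 and 3 with the floor. Leaving out 1 of their arrays, the named accessions had 4636 to 5272 (CS22682), 4357 to 4454 (CS22692), 4267 to 4542 (CS22685), 4144 to 4438 (CS6907), 4015 to 4390 (CS22683), 1928 to 2165 (CS22643) and 1528 to 1671 genes (CS6839). The cause was not tested.

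On and off genes (580) numbered 1114 with a bound of 4-fold and 372 with one of 16-fold. Of 15 relations 11 passed pooled and 7 in period 1 and 7 in period 2 alone. In period 3 alone 2 lost their call, *CBF2* with *COR15A* and salicylic acid with photosynthesis scores. The latter also lost it with normexp and quantile, *PAD4* with *PR1* with the common floor, and *CBF2* with *COR15A* within periods and on second replicates alone. Reversed were *SID2* with *PR1* in period 2 (r = -0.0413), *ACD6* with *PR1* in period 1 (r = -0.00410), *MYB28* with *CYP79F1* in period 2 (r = -0.0173), and anthocyanin with photosynthesis scores with normexp (r = 0.216) and in period 1 (r = 0.463), none of which had passed pooled. The cause was not tested.

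The value tables (identical to the signals used), means over a gene's probes (1 probe per gene), other splits of the groups (2 arrays each) and the relation of *IMA1* with *FER1* were not run.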

Other observations

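The tests below were planned before the result was seen, except that of genotype for photosynthesis and that of a single mislabelled array, which were chosen after it. The label of the genotype test was also made stricter after its value was known.

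The 2 arrays of CS22574 differed in several gene lists at once. Photosynthesis scores were 0.605 on the first array and -0.990 on the second (difference -1.59), and reference gene scores differed by -0.993. Glucosinolate, anthocyanin and cold scores differed by 0.991, 1.198 and 0.844. Against the SD of such differences in the other accessions these were -5.98, -5.76, 4.74, 3.60 and 3.44. On the on and off genes the second array differed from its partner at 36 and from the first array of CS22695 at 33, and its 75th percentile was 1446 units against 636.

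Photosynthesis genes stood 1.57 apart in score between periods 1 and 2. Other bright genes of matched signal moved as well, by 0.475 (95% interval 0.354 to 0.606) against 1.16 for the 23 list genes, so scaling of bright probes could hold part of it, but how much this cannot tell, since with quantile normalization the list genes still moved by 0.330 against 0.0105. A different phase of the clock met the prediction set for it. Within periods the photosynthesis score rose with the level of *LHY* minus that of *TOC1* (r = 0.317, 95% interval 0.0917 to 0.511, permutation p = 0.00465, pooled r = 0.522, with r = 0.788, 0.0557 and 0.185 in periods 1, 2 and 3). The rise was seen mainly in period 1 and hardly in period 2. A relation within periods does not show how much of the gap between them phase holds, so that stays open. In 3 pairs of nearly alike accessions scanned in periods 1 and 2 the score differed by 0.997 (median, range 0.928 to 1.71). The SEs of the median and highest pair were 0.206 and 0.103, which argues against genotype as the whole source, but the lowest (SE 0.797) rests on the unlike arrays of CS22574 and no sequence shows that the pairs share a genotype, so the test cannot tell.

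Genes detected in some accessions and not in others may reflect differences in genome sequence, which would make neighbours alike. The median correlation of 82 neighbouring pairs was 0.239, against 0.0106 in distant pairs and at most 0.0857 in 1000 permutations, and 43.9% of them lay above 0.296, the upper end of the middle 95% of distant pairs. Shared regulation of neighbours would act alike, so the test cannot tell. A split by scanning period was seen in 2.59% of the 580 genes (15), which argues against it as the main source. The test has little power for a gene undetected in few accessions, such as *AOP2*, where all 6 lay in period 2. A part of the period in single genes therefore stays open. Probes with a note of cross-hybridisation made up 3.97% of them against 1.70% of the genes tested, so that source fits for these, while probes without the note were not tested for it.

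The 5 pairs of similar accessions might be near relatives or seed stocks of common origin. On probes of the other classes the pairs differed at a median of 40.5 probes or fewer over their arrays, and all other accessions at a median of 46.5 or more. Relatedness predicts this, but these probes lie on the same arrays as the genes that picked the pairs. Any other source of likeness between the samples would show there as well, so the test cannot single out relatedness. A single mislabelled array is excluded as the source of the likeness, since both arrays of each accession resembled both arrays of the other, with at most 79 of 580 genes differing. Elsewhere 98 or more differed, in part because the pairs were picked by a limit of 91. An exchange of arrays within a pair is not excluded: the first array of CS22693 differed from its partner at 50 genes and from the first array of CS22680 at 24. The stock codes do not name the lines, and sequence data that could show relatedness were not used here.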
